A study of Homo sapiens with 4 samples.

How the data were processed

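RNA was measured in THP-1 cells, a human monocytic leukaemia line whose cells stop dividing and take on macrophage features when protein kinase C is activated. Per the labels, clone SCR4 carried a scrambled hairpin construct and clone SI17 a vector against DAP12, the adaptor protein encoded by TYROBP. Each clone was exposed for 24 h to the solvent DMSO or to 50 nM PMA, a phorbol ester that activates protein kinase C. This gave 4 groups with 1 array each, so there were no replicates. Each construct was represented by 1 clone, so construct and clone cannot be told apart.

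The total RNA was labelled for Affymetrix whole transcript arrays, per the labels' protocols. The deposited values are log2 expression values of probe sets, and the submitters' processing notes name RMA and Affymetrix Expression Console. RMA subtracts background, quantile-normalizes the probe intensities and fits 1 value per probe set. Whether it was run on these 4 arrays together or with others is not given, and this bears on every comparison between arrays. The software versions, the probe set library and the genome build are not given in the sources used here, and no coordinates are printed. All values below start from these deposited log2 values, without further scaling. The 4 arrays had medians of 6.21 (SCR4 with DMSO), 6.39 (SCR4 with PMA), 6.24 (SI17 with DMSO) and 6.23 (SI17 with PMA), and interquartile ranges of 3.84, 3.54, 3.78 and 3.71 in that order. For arrays, their number limits the precision, and no detection calls were used. Values of about 5 or less lie in the lower part of each array's range, where folds are compressed or unsteady.

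Of 33297 probe sets, 19460 had 1 gene symbol in the platform annotation, 1754 had several and 12083 had no listed gene. Symbols were checked through Entrez identifiers against the RefSeq table of GRCh38.p14. This found 19429 of them, 31 were not in that table and kept their name, and 0 were updated. Probe sets with several genes were named for none of them. A further 24 probe sets were left out by a fixed rule that excludes sex-linked marker genes from all results. The remaining probe sets covered 18394 genes, 768 of them with several probe sets, of which the brightest by the mean of the 4 arrays was used. A gene entered the comparisons when its highest value on the 4 arrays was at least 6, which held for 12623 genes.

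The comparisons were the PMA minus DMSO difference in each clone, the SI17 minus SCR4 difference with each agent, and the difference between the PMA changes of the clones (SI17 minus SCR4). With 1 array per group no test across genes was made for these, and genes were counted by a fixed rule of size, at least 2-fold. For a PMA change, "rose" and "fell" are used of genes at least 2-fold the same way in both clones. Means are given with the SD of the 2 clones, or of the 2 agents for clone differences. A limma fit with agent and clone as terms, eBayes moderation and Benjamini-Hochberg adjustment was run as an alternative. It had 1 residual degree of freedom and an estimated prior of 4.52 degrees of freedom. In it the 2 clones stand as the samples of each agent and the 2 agents as those of each clone.

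The 33 gene lists, the comparisons, the filter, the naming rule and the alternatives were fixed before the data were examined, except where stated otherwise. The lists covered DAP12, its partner receptors and signalling genes, macrophage markers, granule and immature myeloid genes, mitosis, DNA replication, histones, cell cycle inhibitors, immediate early genes, cytokines and NF-kB targets, matrix proteases, lysosome, integrins, cholesterol synthesis, lipid handling, interferon response, presentation by MHC class I and class II, osteoclast, microglia, ribosome biogenesis, oxidative phosphorylation, glycolysis, unfolded protein response, protein kinase C feedback, metallothioneins, complement, Fc and scavenger receptors, 5 sets of markers of other cells and control genes. The median of each list was placed among those of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these arrays and is not a p-value. List members that passed the filter are called measured members. Some genes belong to several lists, such as MMP9 and SPP1.

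The genes named were TYROBP and TREM2, the 15 largest rises and the 15 largest falls with PMA by the mean of the clones, the 10 genes most higher and the 10 most lower in SI17 among those at least 2-fold apart with both agents, the 6 largest differences of the PMA change in each direction, and up to 4 members of each list with the largest absolute value of the comparison described. Any member of the DAP12 list could be named. Sex-linked marker genes were left out of the naming.

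The procedures were tested on simulated data, with 12623 genes, 200 of them changed and an array SD of 0.228. The rule for both clones recovered 91.0% of genes changed by 1.5 and 100% of those changed by 3 (log2), with 0 false calls. The rule for the difference of PMA changes recovered 86.0% and 100%, and noise alone brought 376 genes to a 2-fold difference. That noise was set from the spread of the observed differences, so it includes real ones. The limma fit recovered 100% at both sizes with 1 false call. Every simulated gene had the same SD, and for this fit the simulated PMA changes were equal in both clones. In the observed data the residual of the fit holds the differences between the clones' PMA changes, so its rates here cannot be carried over. Of 200 random lists, 5.0% had a median outside the 2.5th to 97.5th percentiles. These lists were drawn from genes with independent noise, so the rate cannot be carried over to genes that vary together.

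The alternatives were cyclic loess, centring of each array on its median, the mean of a gene's probe sets, no filter, a filter at 7, a floor at 5, thresholds of 1.5-fold and 3-fold, and the limma fit. Median centring used the median of each array over the genes passing the filter. Quantile normalization and leaving out each array in turn were added after seeing the data. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.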

Results

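The data set held 4 expression arrays of THP-1 cells, from clone SCR4 (scrambled construct) and clone SI17 (vector against DAP12), each with DMSO or PMA for 24 h. DAP12 is a membrane adaptor that passes signals from receptors such as TREM2 to the kinase SYK, and its loss causes Nasu-Hakola disease, with bone cysts and a dementia. The design compares PMA with DMSO in each clone, the clones with each other under each agent, and the PMA changes of the clones. Over all probe sets the clones correlated at r = 0.990 with DMSO and r = 0.979 with PMA. The agents correlated at r = 0.949 in SCR4 and r = 0.960 in SI17. These are correlations across probe sets, which are not independent replicates.

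TYROBP, the gene targeted in SI17, was lower in SI17 than in SCR4 with both agents. With DMSO its log2 value was 12.04 in SCR4 and 10.37 in SI17, a level 31.4% of that in SCR4. With PMA the values were 13.36 and 12.48, a level of 54.3%. The mean difference was -1.28 ± 0.56 (log2, SD of the 2 agents), and with PMA it was short of 2-fold. Among the genes passing the filter, 30 were lower in SI17 by more than TYROBP with DMSO, and 316 were with PMA. PMA raised TYROBP in both clones, by 1.33 in SCR4 and 2.11 in SI17, so that SI17 with PMA reached a higher value than SCR4 with DMSO.

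Among the partners of DAP12, TREM2 had nearly equal values with DMSO, 6.62 in SCR4 and 6.59 in SI17, and rose with PMA by 1.76 in SCR4 and 4.20 in SI17. With PMA it was therefore 5.32-fold higher in SI17. SIRPB1, another receptor that signals through DAP12, fell by 3.29 in SCR4 and by 1.86 in SI17. Of the 26 members of the list that passed the filter, 5 rose with PMA, 1 fell and 20 did neither. The risers were TYROBP, TREM2, FCER1G (the Fc receptor gamma chain, 1.35 and 1.38 in SCR4 and SI17), CSF1R (the receptor for macrophage colony-stimulating factor, 2.28 and 2.37) and VAV3 (a guanine nucleotide exchange factor, 2.16 and 1.75). The regulatory kinase subunit gene PIK3R1 differed by -1.40 with PMA in SCR4 and by 0.14 in SI17, and was 4.25-fold higher in SI17 with PMA. SYK differed by -1.45 in SCR4 and -0.54 in SI17. HCST, which encodes the related adaptor DAP10, differed between the clones by 0.06 with DMSO and -0.19 with PMA.

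**Figure D1:**
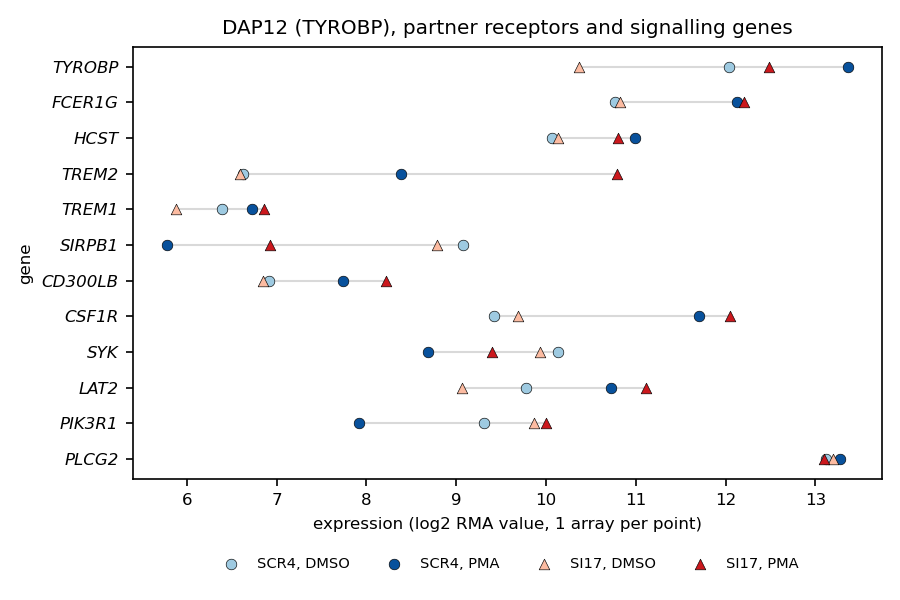
Log2 expression of TYROBP, DAP12 partner receptors and signalling genes (vertical axis) on each of the 4 arrays, with circles for SCR4, triangles for SI17, pale symbols for DMSO and dark symbols for PMA. TYROBP was lower in SI17 with both agents, while TREM2 with PMA stood at 8.38 in SCR4 and 10.79 in SI17.

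PMA was followed in both clones by a fall of nearly all measured cell division genes and a rise of genes of macrophage differentiation, adhesion, matrix breakdown and cytokine production. EMP1, an epithelial membrane protein gene, rose most, by 7.95 ± 0.22 (mean ± SD of the 2 clones, log2; 247-fold). TOP2A, a DNA topoisomerase of dividing cells, fell most, by 5.69 ± 0.58. In all, 767 genes rose and 824 fell in both clones, together 12.6% of the genes passing the filter. Of the 30 genes with the largest rises and falls, 19 had a value under 5 on at least 1 array, and the sizes of their changes are the less certain for it. The other 11 were GPNMB, MMP9, MTSS1, PHLDA1, CD9, SGK1, CCL3, TOP2A, H3C2, TYMS and CCNA2.

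Of 30 measured mitosis genes, 29 fell and 0 rose, with a median change of -4.48. Besides TOP2A, the largest changes of this list were in NUF2 (a kinetochore component, -5.39 ± 0.97), CDK1 (the main mitotic kinase, -5.38 ± 0.85) and KIF11 (a spindle motor, -5.23 ± 0.44). Of 34 DNA replication genes, 33 fell and 0 rose, with a median of -3.28. They included TYMS, which makes thymidylate (-5.36 ± 0.42), and CDC6, which licenses replication origins (-4.67 ± 0.44). All 18 measured replication-dependent histone genes fell, with a median of -3.29, led by H3C2 (-5.46 ± 0.61) and H1-5 (-4.81 ± 0.67). Probe sets of histone genes may share signal with near-identical copies, so single members are uncertain. The other cell division genes among the 15 largest falls were PBK, NEIL3, TTK, SPC25, CCNA2, BUB1 and ANLN, with means from -5.26 to -5.00. PLAC8 fell by 5.63 ± 2.58 and the immature myeloid gene MS4A3 fell by 4.92 ± 0.89. Of 18 cell cycle inhibitor and growth arrest genes, 3 rose and 0 fell, with a median of 0.16. BTG1 rose by 2.38 ± 1.06, CDKN1A, which encodes p21, by 1.96 ± 0.18 and MXD1, a MYC antagonist, by 1.49 ± 0.64.

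Of 21 monocyte and macrophage markers, 12 rose and 1 fell, with a median of 1.70 (2.58 with the filter at 7). GPNMB rose by 6.56 ± 0.51, the gelatinase gene MMP9 by 6.52 ± 0.96, SPP1 (osteopontin) by 5.48 ± 3.16 and the adhesion gene ICAM1 by 4.73 ± 1.11. Of 27 integrin and adhesion genes, 17 rose and 1 fell, with a median of 1.57. They included CD9, a tetraspanin (5.51 ± 0.07), ITGAX, which encodes CD11c (4.22 ± 0.11), and ITGB3 (4.21 ± 0.25). Among 20 matrix proteases and inhibitors, 8 rose and 0 fell (median 0.90, but 2.49 with the filter at 7 and 0.54 without a filter), among them MMP19 (5.04 ± 1.74), the cysteine protease cathepsin L gene CTSL (4.12 ± 0.63) and ADAM9 (3.71 ± 0.07). Of 34 lysosomal genes, 14 rose and 0 fell (median 0.95), such as SCARB2 (3.19 ± 0.62), CTSH (2.76 ± 0.06) and CTSB (2.46 ± 0.57). Of 25 lipid handling genes, 9 rose and 1 fell (median 1.03), including FABP3 (3.74 ± 0.77), LRP1 (3.36 ± 0.36) and ABCA1, a cholesterol exporter (2.91 ± 0.04). Of 15 Fc, scavenger and pattern recognition receptors, 6 rose and 0 fell (median 1.02, but 0.40 without a filter), including TLR1 (3.58 ± 0.53) and the scavenger receptor gene CD36 (2.82 ± 1.20).

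The osteoclast list had 18 measured members, of which 8 rose and 1 fell, with a median of 1.04 (1.98 with the filter at 7). DCSTAMP and OCSTAMP, both needed for cell fusion, rose by 5.57 ± 1.63 and 4.39 ± 0.15. Of 15 microglia genes, 5 rose and 3 fell, with a median of 0.38 (0.16 without a filter). MERTK, a receptor for uptake of dying cells, rose by 3.83 ± 0.62 and ITGAM by 3.04 ± 0.63, while SLC2A5, a fructose transporter gene, fell by 2.92 ± 0.51.

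Of 22 immediate early and AP-1 genes, 10 rose and 0 fell, with a median of 1.0 (1.71 with the filter at 7). FOS rose by 3.88 ± 0.91, JUN by 3.78 ± 0.27, IER3 by 3.77 ± 0.01 and EGR1 by 3.28 ± 0.34. Of 24 genes of protein kinase C and MAPK feedback, 11 rose and 2 fell, with a median of 1.08. PHLDA1 rose by 5.63 ± 0.74 and the phosphatase genes DUSP1, DUSP5 and DUSP6 by 4.21 ± 1.06, 3.77 ± 0.50 and 3.63 ± 0.52. Of 28 cytokine, chemokine and NF-kB target genes, 14 rose and 0 fell, with a median of 1.42. They included CCL3 (5.40 ± 1.68, a gene with near-identical copies), IL1B (4.84 ± 0.48), CCL4 (3.92 ± 1.48) and TNFSF15 (3.35 ± 0.15). The other large rises were those of RGS1, A2M, SLAMF7, HAVCR2, MTSS1, C5AR2 and SGK1, with means from 7.27 to 5.48.

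Of 36 type I interferon response genes, 19 rose and 0 fell, with a median of 1.96. EPSTI1 rose by 4.39 ± 1.69, IFI6 by 4.30 ± 0.18, the antiviral gene MX1 by 4.15 ± 1.14 and OAS3 by 3.90 ± 0.54. Of 19 granule and immature myeloid genes, 7 fell and 0 rose, with a median of -0.89. Besides MS4A3 they included MYB, a transcription factor of progenitors (-3.43 ± 3.18), SERPINB10 (-3.19 ± 0.83) and the receptor gene FLT3 (-2.44 ± 1.33). The medians of the mitosis, DNA replication, histone and granule lists were below those of all 10000 matched random lists. Those of the macrophage, integrin, protease, lysosome, lipid, receptor, osteoclast, immediate early, kinase feedback, cytokine and interferon lists were above all of them.

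**Figure D2:**
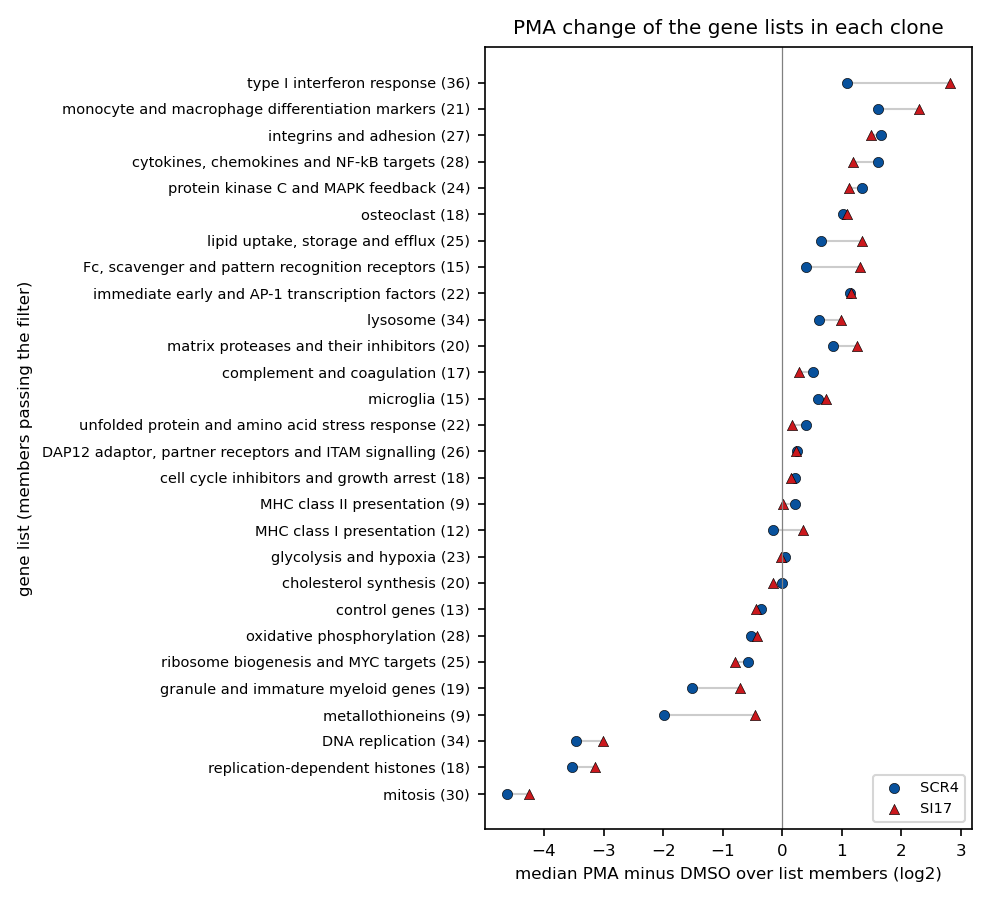
Median PMA minus DMSO change (log2, horizontal axis) over the members of each gene list that passed the filter, in SCR4 (circles) and SI17 (triangles), with the number of members in parentheses. The 5 lists of markers of other cells are left out. Mitosis, histone and DNA replication genes lay lowest in both clones, and the interferon list had medians of 1.09 in SCR4 and 2.82 in SI17.

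In SCR4 alone 1027 genes were at least 2-fold higher with PMA and 1500 lower, and in SI17 alone 1144 were higher and 984 lower. Independent lists of these sizes would share 93.1 higher and 116.9 lower genes, against the 767 and 824 found. The PMA changes correlated at r = 0.847 (Spearman's rho 0.739) across 12623 genes, which are not independent replicates. The limma fit called 1267 genes higher and 1556 lower at a Benjamini-Hochberg adjusted p of 0.05, among them 766 of the 767 and 823 of the 824. Without either SI17 array, the count of lower genes rests on SCR4 and is 1500.

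SI17 and SCR4 also differed without PMA. The neutrophil granule protease gene CTSG was higher in SI17 by 3.25 ± 1.24 (mean ± SD of the 2 agents, log2; 9.54-fold) and the granule peroxidase gene MPO by 2.68 ± 0.82. The homeobox gene ALX1 was lower by a mean of -4.20 ± 1.49 and SERPINF1, which encodes a secreted serpin, by -2.99 ± 0.11. With DMSO alone, CTSG differed by 2.4, MPO by 2.1, ALX1 by -5.2 and SERPINF1 by -2.9. With DMSO, 103 genes were at least 2-fold higher in SI17 and 139 lower. With both agents, 55 were higher and 29 lower.

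The other genes most higher in SI17 were RAB3C (2.89 ± 0.51), the proteoglycan gene GPC3 (2.81 ± 1.20), POGLUT2 (2.77 ± 0.28), MSRB3 (2.69 ± 1.03), LGALS3BP (2.55 ± 1.34), PPP2R3A (2.39 ± 1.11), TDRKH (2.23 ± 0.36) and MOXD1 (2.21 ± 1.51). Those most lower were the homeobox gene LHX9 (-2.53 ± 1.90), the arginine transporter gene SLC7A2 (-2.10 ± 1.33), CD4, which monocytes also carry (-2.06 ± 0.32), the TRAIL receptor gene TNFRSF10B (-1.96 ± 0.71), the acute phase gene ORM1 (-1.89 ± 0.55), TANC1 (-1.81 ± 0.50), MSC (-1.80 ± 0.79) and SH2D4A (-1.79 ± 0.22). RAB3C, POGLUT2, MSRB3, PPP2R3A, MOXD1, ALX1 and SLC7A2 had a value under 5 on at least 1 array. With a floor at 5 the difference of PPP2R3A was 2.02 with DMSO and 0.96 with PMA, and that of MOXD1 was 2.43 and 0.77. Both genes were then short of 2-fold with PMA. ALX1 stood at 9.07 in SCR4 with DMSO and 3.82 in SI17, and CTSG at 9.97 and 12.35.

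Granule and immature myeloid genes had a median clone difference with DMSO of 0.27 (percentile 99.99 among the random lists), with 2 of 19 members at least 2-fold higher with both agents, CTSG and MPO. The granule protease homolog gene AZU1 was higher by 0.96 with DMSO and 1.09 with PMA. In the other direction, 1 member, SERPINB10, was at least 2-fold lower in SI17 with DMSO (-1.30), and FLT3 differed by -0.97. Cytokine, chemokine and NF-kB target genes had a mean difference over both agents with a median of -0.34, below all random lists. With DMSO alone the median was -0.08 (percentile 6.21), within the range of the random lists, and with PMA it was -0.42. Of the 28 genes, 0 were at least 2-fold lower with both agents. CCL20 differed by -0.41 with DMSO and -2.53 with PMA, IL1B by -0.79 and -1.47, and TNF by -0.98 and -0.85. DNA replication genes and histones stood lower in SI17 with DMSO, by medians of -0.24 and -0.25 (percentiles 0.02 and 0.13), with 0 members of either list at least 2-fold lower. RASGRP3, an activator of RAS that binds phorbol esters, was at least 2-fold higher in SI17 with both agents (2.34 and 1.62), but its value in SCR4 with DMSO was 3.91, and with a floor at 5 the first of these was 1.25.

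Independent lists would share 5.23 higher and 2.60 lower genes between the agents, against the 55 and 29 found. The clone differences with DMSO and with PMA correlated at r = 0.316 (rho 0.283) across genes, which are not independent replicates. In the limma fit 0 genes had an adjusted p under 0.05 for clone, with 764 higher and 569 lower at an unadjusted p of 0.05, and the lowest adjusted p was 0.115. Without a PMA array the counts rest on DMSO alone and are 103 higher and 139 lower, and without a DMSO array they are 641 and 236.

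With PMA the clones stood further apart, and most of the larger differences were upward in SI17. Type I interferon response genes had more upward PMA changes in SI17. The progenitor and myeloid transcription factor genes MYB and IRF8 changed by -5.68 and -5.06 with PMA in SCR4, and by -1.18 and -0.32 in SI17. With PMA 641 genes were at least 2-fold higher in SI17 and 236 lower. The PMA change itself was at least 2-fold more upward in SI17 for 631 genes and more downward for 224, so 73.8% lay upward. This share was 84.1% after cyclic loess and 59.6% after median centring.

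The largest upward difference was in PLA2G7, which encodes a lipoprotein-associated phospholipase. Its value changed by 0.24 in SCR4 and 6.04 in SI17, and with PMA it stood at 3.77 and 10.44. MNDA, a myeloid nuclear gene induced by interferon, changed by -5.50 in SCR4 and -0.28 in SI17. IRF8, a transcription factor of the monocyte lineage, stood with PMA at 7.12 in SCR4 and 11.54 in SI17. MYB stood at 5.73 and 10.41. The relaxin receptor gene RXFP1 changed by -4.14 and 0.45. The interferon-induced gene IFI44 changed by 1.15 and 5.88. In the other direction, NT5E, which encodes the ectonucleotidase CD73, changed by 4.99 in SCR4 and 0.97 in SI17, and was 2.35 higher in SI17 with DMSO. MMP19 changed by 6.27 and 3.81, the signalling adaptor genes TRAF1 and IRAK2 by 3.04 and 0.46 and by 4.02 and 1.47, CLMP by 3.35 and 0.57, and TBC1D30 by 0.87 and -2.37. TBC1D30 also differed between the clones with DMSO, by 2.27. PLA2G7, MNDA, IFI44 and NT5E had a value under 5 on at least 1 array.

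All 36 measured interferon response genes had a more upward PMA change in SI17, 31 of them by at least 2-fold, with a median difference of 1.59. With DMSO the list differed between the clones by a median of 0.04 (percentile 73.0 among the random lists), and with PMA by 1.71, above all of them. After IFI44 the largest differences were in TRIM22 (-1.91 in SCR4 and 2.48 in SI17), IFI44L (1.34 and 4.99) and HERC5 (-2.01 and 1.39). TRIM22 and HERC5 also differed between the clones with DMSO, by -1.277 and -0.645. IFI44 and IFI44L lay under 5 on 3 of the 4 arrays, and with a floor at 5 they changed by 0 in SCR4 and by 4.38 and 3.42 in SI17. IFITM1 stood 3.25 and IFIT2 2.98 above SCR4 with PMA, against 0.92 and 1.17 with DMSO. Several of these genes belong to families of similar sequence, so single members are uncertain.

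**Figure D3:**
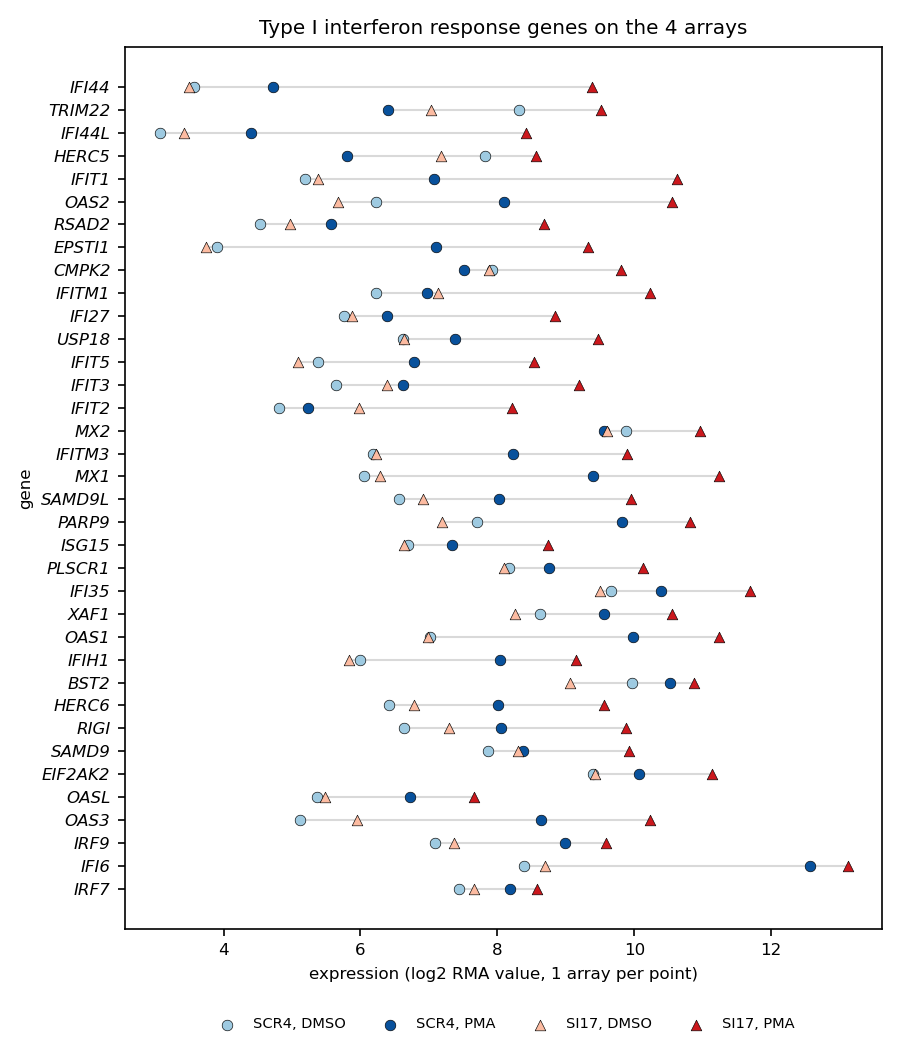
Log2 expression of the 36 measured type I interferon response genes (vertical axis, sorted by the difference of the PMA changes) on each of the 4 arrays, with circles for SCR4, triangles for SI17, pale symbols for DMSO and dark symbols for PMA. With PMA, SI17 lay above SCR4 for every gene, and 29 of them were at least 2-fold higher.

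Of 19 granule and immature myeloid genes, 16 had a more upward PMA change in SI17, 9 by at least 2-fold and 1 by at least 2-fold downward, with a median difference of 0.91. After MYB the largest were FLT3 (-3.38 in SCR4 and -1.50 in SI17), CTSG (-2.60 and -0.85) and CEBPA, a transcription factor of granulocyte and monocyte precursors (-1.77 and -0.26). FLT3 differed between the clones by -0.97 with DMSO and 0.91 with PMA, so its value rests in part on the DMSO arrays. The mitosis list, of which 29 of 30 members fell in both clones, had medians of -4.62 in SCR4 and -4.26 in SI17 and a median difference of 0.44, which was 0.22 with a floor at 5. DNA replication genes had a median difference of 0.48, with SI17 lower than SCR4 by a median of -0.24 with DMSO and higher by 0.19 with PMA (0.13 after median centring), so that the value does not rest on the PMA arrays alone.

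Of 15 microglia genes, 14 had a more upward change in SI17, 4 by at least 2-fold, with a median difference of 0.72 (0.25 without a filter). The fractalkine receptor gene CX3CR1 changed by -3.24 in SCR4 and 0.78 in SI17, TGFBR1 by 0.83 and 2.51, and MS4A6A by -3.36 and -1.75. Lipid handling genes had a median difference of 0.50, with 21 of 25 more upward in SI17, among them LPL, which encodes lipoprotein lipase (0.66 in SCR4 and 4.03 in SI17), CD36 (1.97 and 3.67) and ALOX5AP (-0.41 and 1.20). The lipid list differed between the clones by a median of -0.196 with DMSO (percentile 0.35) and 0.455 with PMA. LPL differed by -1.66 with DMSO and 1.71 with PMA, and CD36 by -0.71 and 0.99. The values of the list and of both genes therefore rest in part on the DMSO arrays. Among macrophage markers (median difference 0.35, or 0.59 with the filter at 7, 6 upward and 2 downward by at least 2-fold), SPP1 changed by 3.25 and 7.72 and CD14, the coreceptor for endotoxin, by 0.39 and 2.30. Lysosomal genes had a median difference of 0.35, led by LGMN (0.40 and 2.60), and Fc, scavenger and pattern recognition receptors 0.48, where the IgA receptor gene FCAR went the other way (3.37 and 1.30). The DAP12 list had a median difference of 0.18, which was 0.07 after median centring and 0.33 with the filter at 7.

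Cytokine, chemokine and NF-kB target genes had a median difference of -0.26 (-0.16 after cyclic loess), with 3 upward and 5 downward by at least 2-fold. CCL3 changed by 6.58 in SCR4 and 4.21 in SI17, CCL20 by 2.93 and 0.81, and NFKB2 by 2.81 and 1.22. CCL4 changed by 4.96 and 2.87, but this rests on its DMSO values of 2.96 and 4.94, both under 5, while its PMA values were 7.93 and 7.81. With a floor at 5 the difference of its PMA changes was -0.12 in place of -2.09. Immediate early genes had a median of -0.25 (-0.08 after cyclic loess), with FOS at 4.52 and 3.24 but ZFP36 at 0.50 and 1.58. Matrix proteases had a median of -0.17 (-0.28 after median centring), with MMP9 at 7.20 and 5.85. Osteoclast genes went both ways, with SPP1 upward and DCSTAMP downward (6.72 in SCR4 and 4.42 in SI17, or 5.32 and 3.88 with a floor at 5), and their median of -0.02 changed sign under 3 alternatives. Integrin genes had a median of 0.10 that changed sign under 2, with ITGAL at -0.60 and 2.07 and ICAM1 at 5.52 and 3.94. Kinase feedback genes had a median of 0.12 (0.01 after median centring), with DUSP1 at 4.96 and 3.46 and PRKCB at -2.26 and -0.96, and histones 0.23 (0.12 after median centring).

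**Figure D4:**
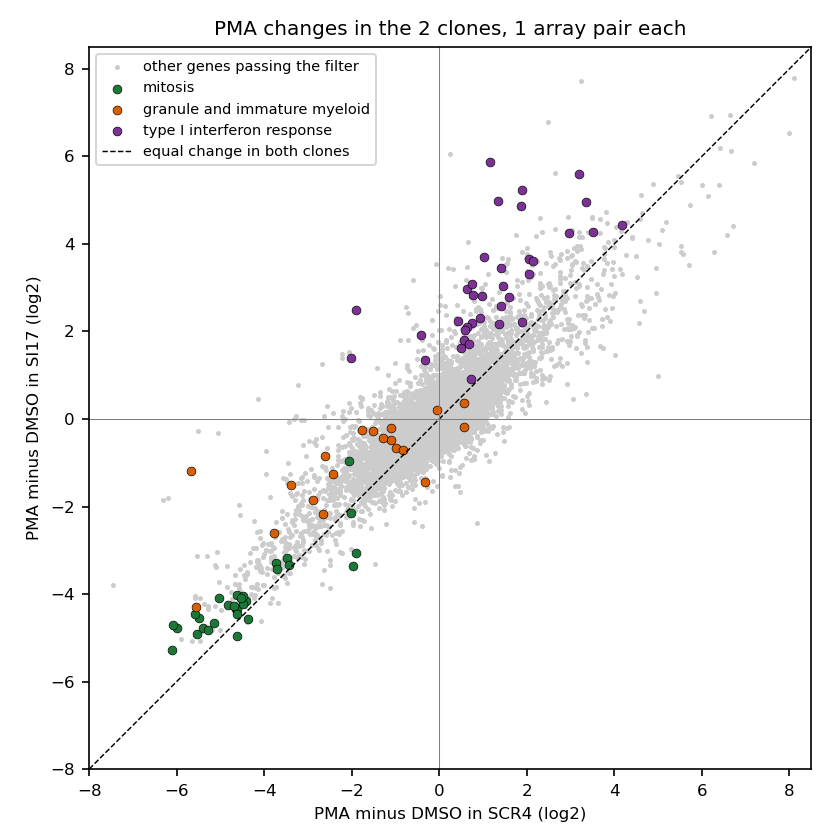
PMA minus DMSO change (log2) of each gene that passed the filter in SCR4 (horizontal axis) and SI17 (vertical axis), with 3 gene lists coloured and a dashed line for equal change in both clones. Mitosis genes lay at strongly negative values in both clones, and all 36 interferon genes lay above the line.

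Among the list members named above, EPSTI1, IFIT2, SERPINB10, IL1B, CCL20 and MS4A6A also had a value under 5 on at least 1 array. The difference of PMA changes rests on all 4 arrays and has no replicate check. Noise simulated with the spread of the observed differences brought 376 genes to a 2-fold difference, against the 855 found. That noise had the same SD for every gene, whereas dim genes may vary more. The comparison therefore does not tell how many of the 855 lie beyond noise.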

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

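The interferon test with DMSO alone, the comparison of the shares of expression kept, and the count of clones were chosen only after the results were seen, and quantile normalization was added after seeing the data.

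For 9 genes the clones moved opposite ways with PMA by at least 2-fold, downward in SCR4 and upward in SI17, and this difference was not tested. The PMA change of SI17 minus that of SCR4 (log2) was 4.39 for TRIM22, 3.94 for CD244, 3.72 for SLA, 3.60 for ENTPD1, 3.60 for TMT1B, 3.40 for HERC5, 2.58 for CD84, 2.29 for SLFN11 and 2.17 for KCTD12. All 9 already stood lower in SI17 with DMSO, from -0.321 for CD84 to -2.255 for CD244. With PMA they stood higher, from 1.461 for KCTD12 to 3.115 for TRIM22, so these values rest in part on the DMSO arrays. Apart from TRIM22 and HERC5, which belong to the interferon list, these genes were chosen after their values were seen. CD244 and CD84 encode receptors of the SLAM family, and ENTPD1 encodes the ectonucleotidase CD39. With 0 genes moving the other way, the 9 are also among the 631 with a more upward change in SI17.

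Probe sets without a listed gene were outside the comparisons of genes. Of the 5269 that passed the filter, 126 were at least 2-fold higher and 87 lower with PMA in both clones, together 4.04%, against 12.6% of named genes. What they measure is not given in the sources used here.

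All 36 measured interferon response genes had a more upward PMA change in SI17 than in SCR4, 31 of them by at least 2-fold. SCR4 also carried a hairpin construct, so an effect of hairpin vectors shared by both clones cannot be seen here. An effect of the SI17 vector alone, present without PMA, would set SI17 about as far above SCR4 with DMSO as with PMA. The median clone difference was 0.039 (log2) with DMSO and 1.71 with PMA, with an SD of members of 0.50 and 1.03. With DMSO, 1 member was at least 2-fold higher in SI17 and 1 lower. Such an effect is argued against for the list as a set, but the same values make up the pattern, so this is not a separate test. Array scale is argued against as the whole cause, since the median difference of the PMA changes was 1.61 after quantile normalization, against 1.59 before. Knockdown of DAP12 or clone cannot be told apart, with 1 clone per construct. A stronger interferon response to PMA in SI17, from either, stays open as a hypothesis, as does an interaction of the vector with PMA, which was not tested.

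Of 19 granule and immature myeloid genes, 16 had a more upward PMA change in SI17, 9 by at least 2-fold, and 1 was more downward by at least 2-fold. Array scale is argued against as the whole cause by a median difference of 1.08 after quantile normalization, against 0.91 before. A share of SI17 cells that did not respond and kept cycling would hold mitosis and immature genes alike, and this is argued against. Mitosis genes kept a median of 4.06% of their DMSO level in SCR4 and 5.24% in SI17, and all 19 immature myeloid genes 35.2% and 61.3%. The gain in SI17 had a median of 1.21 percentage points over mitosis genes (quartiles 0.87 to 2.03) and 17.3 over the 19 (5.76 to 36.0). A weaker response of the immature programme to PMA in SI17 stays open as a hypothesis, and knockdown of DAP12 or clone cannot be told apart as its source, with 1 clone per construct.

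More genes had a more upward than a more downward PMA change in SI17, 73.8% of those at least 2-fold apart. The array of SCR4 with PMA had the narrowest interquartile range, 3.54, but after quantile normalization the upward share was 78.4%, which argues against that narrower spread as the whole cause. Centring each array on its median over the genes passing the filter lowered the share to 59.6%. Over these genes the median was 7.85 for SCR4 with PMA and 7.91 to 7.98 on the other arrays. Over all probe sets the array of SCR4 with PMA instead had the highest median, 6.39. A shift of the middle of that array may account for part of the share, but its direction depends on the filter. This part stays open, as does a difference between the clones or constructs, which was not tested for the asymmetry.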

How the results depend on the processing

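Quantile normalization and leaving out each array in turn were chosen after seeing the data. Under the alternatives run for them, the correlations and the TYROBP difference kept their sign, and TYROBP ranged from -1.31 to -1.28. Of the 119 values of main results under alternatives, 90 stayed within the limits set (counts within 1.5 times, correlations within 0.05), and 29 did not. Cyclic loess, quantile normalization, the mean of probe sets, the filter at 7 and the floor at 5 moved 0 main results beyond them. The count of genes with a more downward PMA change in SI17 was 338 after median centring and 338 without the filter. Without the filter the correlation of the clone differences was 0.259, with more dim genes included.

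By construction the counts followed the threshold. At 1.5-fold, 1331 genes were higher and 1672 lower with PMA in both clones, 256 higher and 165 lower in SI17 with both agents, and 1604 more upward and 1149 more downward in PMA change. At 3-fold the counts were 402, 431, 16, 5, 207 and 51 in that order. The limma fit at an adjusted p of 0.05 compares PMA with DMSO within the clones, and gave 1267 and 1556 genes for PMA, and 0 and 0 for clone (764 and 569 unadjusted). With an array left out a count rests on the remaining pair: 984 to 1500 genes lower with PMA, and 103 to 641 higher and 139 to 236 lower in SI17. Genes higher with PMA then numbered 1027 to 1144. The difference of PMA changes cannot be computed once any of the 4 arrays is left out.

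Of 320 values of named genes, 304 moved by less than the SD of their 2 clones or agents (0.41 for differences of PMA changes) and 16 by more, mostly with the floor at 5. Where the clones or agents lay far apart this limit is wide, such as 3.16 for SPP1, and staying within it says little. Values of list medians moved by less than the spread set for a list of their size in 574 cases and by more in 119. Of 99 list medians, 14 changed sign under an alternative, all of them within 0.28 of 0. Over the genes passing the filter, median centring moved the median SCR4 PMA change from 0.02 to 0.15. It moved the median difference of PMA changes to -0.11, and cyclic loess moved the latter to 0.10. Genes near the lower end of the signal are the least certain: with a floor at 5 the mean PMA change of EMP1 was 7.34 in place of 7.95.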

Other observations

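No hypothesis beyond those above was tested here, and every value below is a description of single arrays. Metallothioneins, small metal-binding proteins, fell with PMA in 3 of 9 measured members and rose in 0, with a median of -1.15. The median change was -1.98 in SCR4 and -0.45 in SI17. All 9 had a more upward PMA change in SI17, 7 by at least 2-fold, with a median difference of 1.39. Between the clones the list differed by a median of -0.33 with DMSO, with 1 member at least 2-fold lower in SI17. With PMA it differed by 0.97, with 4 members at least 2-fold higher. The difference of PMA changes thus rests in part on the DMSO arrays. MT1E changed by -3.45 in SCR4 and -1.01 in SI17, MT1F by -3.41 and -1.26, MT1G by -3.49 and -1.37, and MT1M by -2.21 and 0.18. Members of this family are similar in sequence, so single values are uncertain. Ribosome biogenesis and MYC target genes had a median PMA change of -0.71, below all 10000 random lists, with 2 of 25 falling in both clones, CAD by 1.63 ± 0.34 and FBL by 1.30 ± 0.11. Their median clone difference over both agents was -0.31, with 0 of 25 at least 2-fold lower in SI17 with both agents, and MYC changed by -0.34 in SCR4 and -1.44 in SI17. Of 22 unfolded protein and amino acid stress genes, 1 rose (DDIT3, 1.58 ± 0.06) and 2 fell (the serine synthesis genes PHGDH, -3.17 ± 0.96, and PSAT1, -2.19 ± 0.31). Their median clone difference was -0.29, with 0 of 22 at least 2-fold lower with both agents and ASNS lower in SI17 by a mean of -1.06. With DMSO, 2 members were at least 2-fold higher in SI17 and 0 lower, and with PMA 0 were higher and 3 lower.

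Cholesterol synthesis genes were higher in SI17 with DMSO by a median of 0.38, above all random lists, although 0 of 20 reached 2-fold. ACAT2 was higher by 0.63 with DMSO and 0.75 with PMA, and SC5D by 0.91 and 0.31. With PMA, SQLE, an epoxidase of the pathway, rose by 1.62 ± 0.33, LSS fell by 1.47 ± 0.11, and the median of the list, -0.06, changed sign under 3 alternatives. Oxidative phosphorylation genes had a median PMA change of -0.48 (percentile 0.17), with 0 of 28 at least 2-fold in both clones. Of 23 glycolysis and hypoxia genes, 3 rose, the glucose transporter gene SLC2A3 by 3.28 ± 0.35, ENO2 by 1.89 ± 0.11 and ADM by 1.59 ± 0.05. Of 17 complement and coagulation genes, 3 rose and 0 fell (median 0.40, but 0.67 with the filter at 7 and 0.21 without a filter), namely the anaphylatoxin receptor genes C5AR1 (5.13 ± 0.34) and C3AR1 (4.70 ± 0.55) and CD59 (1.68 ± 0.95). Of 9 MHC class II presentation genes, 3 rose, none of them an HLA gene: CD86 by 3.49 ± 0.59, CD40 by 1.95 ± 0.26 and CTSS by 1.45 ± 0.36. RFX5, a regulator of HLA class II genes, differed by -0.36 and -0.37. Of 12 MHC class I presentation genes 0 rose or fell, and their median difference between the clones' PMA changes was 0.51 (percentile 99.92). C5AR1 and CD86 had a value under 5 on at least 1 array. PSMB9, an immunoproteasome subunit, changed by -1.03 in SCR4 and 0.53 in SI17.

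Markers of other cells were mostly below the filter. The T and NK list kept 4 of 14 members, of which 0 rose or fell, and CD4 was the member at least 2-fold lower in SI17. The B cell list kept 5 of 10, and CD22, which rose by 2.24 ± 0.20 from values of about 5, was the 1 riser. The epithelial, fibroblast and erythroid lists kept 4, 5 and 3 members, of which 0 rose or fell, and THY1 differed by -1.46 with PMA in SCR4 and -0.09 in SI17. The median PMA changes of these 5 lists were 0.17, 0.24, 0.14, 0.08 and 0.04 in that order. Under the alternatives they lay between -0.20 and 0.32, and the last 2 changed sign. Of 13 control genes 0 rose or fell, with a median of -0.30, and HPRT1 differed by -1.17 in SCR4 and -0.65 in SI17. The PMA change was more upward in SI17 for 10 of the 13. Their median difference of PMA changes was 0.23 (percentile 93.2, and 0.12 after median centring). That is as large as the value of the histone list and larger than those of the DAP12, integrin and kinase feedback lists.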
